A study of Mus musculus with 12 samples.

How the data were processed

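RNA from 4 mouse lung adenocarcinoma cell lines was measured on 12 one-colour Affymetrix 3-prime expression arrays, 3 per line. Per the labels, KC1, KC2 and KC3 are highly metastatic and KC4 is poorly metastatic. The 3 arrays of a line are biological replicates by the same labels. The labels speak of 6 primary tumours from 4 mice and do not assign the lines to mice, so the fits that take lines as units rest on the untested premise that the lines are independent. The labels give the same genotype for every sample, a heterozygous K-rasLA1 allele together with loss of both copies of Cdkn1a, the gene of the cell-cycle inhibitor p21. The lines were grown in RPMI medium with serum. Total RNA was labelled with biotin after the array maker's protocol, per the labels.

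The deposited table holds one linear intensity per probe set and array, for 45101 probe sets. The software behind the deposited intensity values is not given in the sources used here. From the values themselves, the scale is linear, and no probe set was centred. The mean after trimming 2% at each end ran only from 500.002 to 500.003 over the arrays, the pattern left by scaling every array to one target. The median signal per array was 115, 114 and 119 in KC1 replicates 1 to 3, 128, 112 and 117 in KC2, 96.1, 94.5 and 112 in KC3, and 106, 123 and 111 in KC4. Such scaling fixes the average brightness, so a change in total messenger RNA per cell would not be seen. Scanner files, hybridisation batches and detection calls were not used here, and which background correction was applied stays unknown.

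Signals under 16 were set to 16 and log2 values were taken, so the lowest possible value is 4.00. On each array 15.3% to 20.0% of the probe sets lay at or under this floor. After 64 control probe sets were left out, 45037 remained. Gene names came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 were not listed there. Of those with 1 symbol, 34741 matched a gene identifier of the RefSeq gene table for assembly GRCm38.p6, which changed 0 symbols and was otherwise used only to find neighbouring genes. For each of the 18193 genes the probe set with the highest mean was used; 9010 genes had more than 1 probe set. No genome build is named for the values, so no coordinates are given. Probe sets with the ending x_at or s_at can pick up related transcripts, and those named for Krt14, Ildr2, Cldn3, Ltbp3, Sulf2, Snai2, Rbpms, Vegfd, Fdft1, Itga5 and Xist are of this kind.

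Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per line, all 12 arrays), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1. The contrast of metastatic class was the mean of KC1, KC2 and KC3 minus KC4. A gene set a line apart when it was called against each of the other 3 lines in the same direction. The prior degrees of freedom were 0.811, and 659 genes lay at the floor on all arrays. On simulated data with 18193 genes and 50 genes changed at each size, the contrast of metastatic class called 96% of the genes changed by log2 1.5, 98% at 2, 98% at 3 and 100% at 4, with 2 false calls. The rule of calls against each line found 92%, 94%, 98% and 100%, with 0 false calls. Changes were planted only in genes of higher mean signal, so these shares do not cover dim genes. Unchanged genes had the same mean in every line, so the false calls say nothing of differences between lines.

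The 34 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 34 lists. Named genes followed a rule fixed at the same time. It takes the 12 genes higher and 12 lower in KC1, KC2 and KC3 than in KC4 with the largest value of the smallest of the 3 differences. It adds up to 4 such genes per list, or up to 2 called in the contrast of class alone, 4 higher and 4 lower genes for each highly metastatic line, Cdkn1a, and the sex-chromosome genes. Other genes are named only as members of a counted group, and these were chosen after their values were seen. The K-ras transcript and 62 other listed genes had no single-gene probe set in the files used here and were not analysed here.

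Alternatives covered the replicate number as a block, leaving out each array or each highly metastatic line, other choices of probe set, a filter on dim genes, quantile normalization, median centring, another prior, other minimum differences and 3 other treatments of the line. A pseudocount of 16 in place of the floor, a floor of 64, the lists without each highly metastatic line and the lists for each line against the mean of the others were added after the data had been examined. Figures were drawn with matplotlib 3.10.9.

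The precision is limited by 3 arrays per line. The median SD between arrays of a line was 0.44 on the log2 scale for genes with a mean under 6, 0.31 from 6 to 8, 0.14 from 8 to 10, 0.095 from 10 to 12 and 0.093 over 12. The p-values measure the spread between cultures of a line. They carry no information on the spread between tumours, because the poorly metastatic class is 1 line, and line, any batch of that line and metastatic class cannot be told apart.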

Results

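Gene expression was measured in 4 cell lines grown from primary lung adenocarcinomas of mice. The mice carry a K-rasLA1 allele, which switches on mutant K-ras in scattered cells, and lack Cdkn1a. KC1, KC2 and KC3 were labelled highly metastatic and KC4 poorly metastatic. Each line had 3 biological replicates on 1 array each. Values are log2 signals with a floor of 4.00, given as mean ± SD (n = 3), for 18193 genes. Arrays of one line correlated across genes with a mean Spearman rho of 0.980 to 0.982, and arrays of different lines with 0.944 (KC2 and KC4) to 0.961 (KC1 and KC2). Genes are not independent replicates. The 5-prime control probe set for 18S ribosomal RNA had a mean signal of 3305 in KC4 against 490 in the other lines. This difference, 2.75 on the log2 scale, ran along with every KC4 difference below. The log2 ratio of 3-prime to 5-prime signal in KC4 minus the mean of the others was -0.058 for the Actb controls and 0.019 for the Gapdh controls.

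The mice were altered in Cdkn1a, so its probe sets were read first. One of its 2 probe sets gave a signal of 7800 ± 457 in KC1, 5900 ± 504 in KC2, 6720 ± 507 in KC3 and 4360 ± 478 in KC4. The other gave 12.8 ± 1.92, 7.13 ± 0.757, 6.39 ± 3.52 and 9.24 ± 2.79, all under the floor. The part of the gene that each covers is not given in the sources used here. A probe set outside the deleted part does not check the genotype. On the brighter one the highly metastatic lines lay 0.64 (SE 0.079, limma adjusted p = 0.000239) above KC4, under the minimum difference for a call.

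The main question of the design was which genes differ between the highly and the poorly metastatic lines. Pgrmc1, a heme-binding membrane protein, showed the largest gap among genes higher in every highly metastatic line. Its signal was 5180 ± 163 in KC1, 5620 ± 359 in KC2 and 3500 ± 93.2 in KC3 against 87.2 ± 22.6 in KC4, a 54.9-fold mean difference. Csf2, the cytokine GM-CSF, reached 1010 ± 75.2, 1180 ± 72.2 and 1130 ± 84.7 against 90.8 ± 71.1. The chemokine gene Ppbp had 1040 ± 67, 2230 ± 154 and 335 ± 41.5 against 61.1 ± 45.9. Smarca2, an ATPase of the SWI/SNF chromatin remodelling complex, and Fhit, a gene often lost in lung cancer, lay at the floor on all KC4 arrays on the probe sets used. On these the highly metastatic lines were higher by at least 4.28 and 4.59 on the log2 scale. A second, dimmer Smarca2 probe set did not differ (6.58, 6.58 and 6.23 in KC1 to KC3 against 6.58 in KC4, difference -0.11), so the Smarca2 difference rests on 1 probe set. In the other direction, the basal keratin Krt14 had a signal of 4840 ± 365 in KC4 against 34.1 ± 19.4, 9.56 ± 5.65 and 269 ± 24.9. The secreted ligand Bmp4 had 3540 ± 314 against 124 ± 14.8, 173 ± 9.17 and 150 ± 15.9.

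In total 991 genes were called between the classes, 523 higher and 468 lower in the highly metastatic lines. Of the 18193 genes, 296 set KC4 apart from each highly metastatic line, 169 higher and 127 lower in those lines. The further genes of the leading 12 that were higher were the membrane proteins Tm4sf1 (at least 5.32 on the log2 scale, KC4 being at the floor), Tspan1 (4.00) and Gpa33 (4.11). They also held the water channel Aqp8 (4.53), the ubiquitin ligase Rnf128 (4.31), Ctla2a (3.50) and Mb21d2 (3.67). The further genes of the leading 12 that were lower were the transcription factors Runx3 (-4.57), Myrf (-4.60) and Pparg (-4.24), and the water channel Aqp1 (-4.39). They also held the neuronal tubulin Tubb3 (-4.41), the aldehyde dehydrogenase Aldh3a1 (-3.77), Ccn4 (-3.79), Mxra8 (-4.09), Ildr2 (-4.34) and Gm2115 (-4.10). The differences of Mb21d2, Runx3, Pparg, Tubb3 and Ccn4 are lower bounds in size, since 1 KC4 array for Mb21d2 and 6, 2, 3 and 7 arrays of the other lines for the rest lay at the floor. Among these 24 genes the largest limma adjusted p was 0.000216, for Csf2, with 1 coefficient per line. With the line as a random block Csf2 (adjusted p = 0.0616) and Ppbp (0.0837) lost their calls. Of 14 other probe sets of these genes, 11 were called in the same direction, 0 in the opposite one and 3 not at all, 1 each of Smarca2 (-0.11), Mb21d2 (-0.03) and Tm4sf1 (0.65). The 3 contrasts share the KC4 arrays, and 20 simulations with unchanged lines gave 0 genes in all 3, while independent lists of these sizes would share 1.91. The simulated lines differed in no gene, so the 0 does not measure what shared arrays add among real differences. Part of the overlap may come from the shared arrays, since 3 arrays cannot be split so that each part keeps 2. For the other lines independent lists would share 1.25 (KC1), 2.27 (KC2) and 3.6 (KC3), against 157, 334 and 434 genes found. An excess over independent lists is thus not particular to KC4. Of the 991 genes, 144 had a KC4 mean within the range of the 3 other lines. With line means as replicates KC4 is 1 value, so that fit shows no class difference and cannot tell few lines from a lack of differences. With the line as a random block limma called 249 genes, 152 higher and 97 lower. This fit applies 1 correlation between arrays of a line to all genes. The poorly metastatic class has 1 line, so its spread between lines is not measured. Calls kept in this fit, here or below, are thus not shown to hold across lines.

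**Figure D1:**
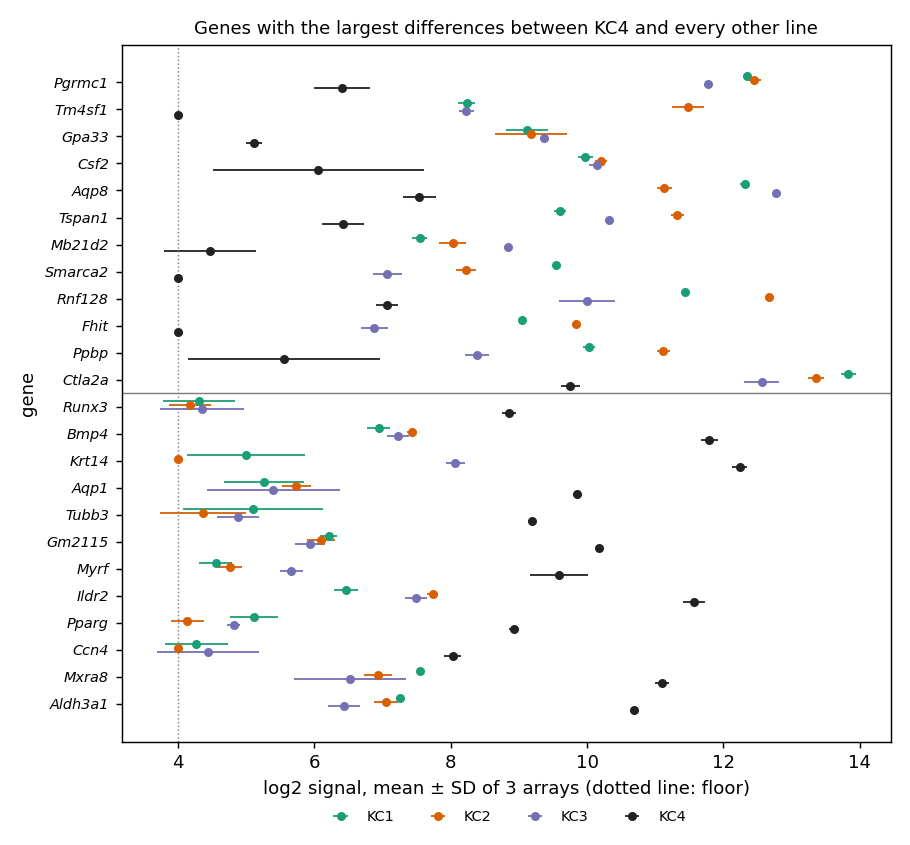
Log2 signal (horizontal axis) of the 24 genes with the largest differences between KC4 and every highly metastatic line (rows), as the mean and SD of 3 arrays per line. KC4 lies to the left of the 3 other lines in the upper 12 genes and to the right in the lower 12; the dotted line marks the floor at 4.00.

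Metastatic class and line are the same thing for KC4, so the genes that set each line apart were counted in the same way. KC4 was not the most distinct line: 157 genes set KC1 apart, 334 KC2, 434 KC3 and 296 KC4. In KC1, 131 were higher and 26 lower. They were led by Dsc2, a desmosomal cadherin (8.84 ± 0.61, at the floor in the other 3 lines), Zfhx4 (8.26 ± 0.14, likewise), Nr2f1 (9.40 ± 0.20) and Mdfic (10.70 ± 0.05). The lower side was led by the estrogen receptor gene Esr1 (5.27 ± 1.34, though 6.33 against 6.14 to 6.53 on another probe set), Bmp2 (5.67 ± 0.05), Bdkrb2 (5.76 ± 0.41) and Mettl7b (4.16 ± 0.25). In KC2, 149 were higher, led by Cpm (8.89 ± 0.25), Tcf24 (9.75 ± 0.14), Sgpp2 (9.60 ± 0.08) and Cpne2 (8.73 ± 0.23). Another 185 were lower, led by Smad1, a transducer of BMP signals (5.23 ± 1.10 against 10.78 to 11.34 in the other lines), Oat (5.41 ± 1.29), Sulf2 (4.91 ± 0.28) and the transcription factor Snai2 (4.29 ± 0.31 against 8.90 to 10.66).

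In KC3, 153 genes were higher and 281 lower. With each array centred on its median the split turned to 304 higher and 195 lower, while quantile normalization kept its direction (169 higher and 240 lower). Which direction prevails in KC3 thus depends on the scaling. The higher ones were led by Cldn9 (12.44 ± 0.10 against 6.06 to 8.25), the non-coding RNA Pvt1 (13.47 ± 0.10 against 8.20 to 9.64), the chemokine gene Ccl20 (10.15 ± 0.08) and Tmprss13 (9.25 ± 0.16). The lower ones were led by Cyba, a subunit of the NADPH oxidase (at the floor against 10.71 to 11.94), Rbpms (5.40 ± 0.27), the proteoglycan Bgn (7.14 ± 0.29 against 12.28 to 13.39) and Serpinh1, a collagen chaperone (7.26 ± 0.08 against 12.01 to 12.81). With 4 lines there are 4 ways to single a line out, so these counts cannot show that a line stands apart more than chance allows. A fit with lines as units was run for KC4 alone. The count for KC1 fell to 41 (27 higher and 14 lower) without the dimmer 50% of the genes. That filter uses the mean over all arrays, so it removes genes high in 1 line alone more readily than genes low in 1 line alone. When a log2 difference of 2 was demanded, the counts were 43, 74, 77 and 81 for KC1 to KC4, and KC4 then had the highest.

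**Figure D2:**
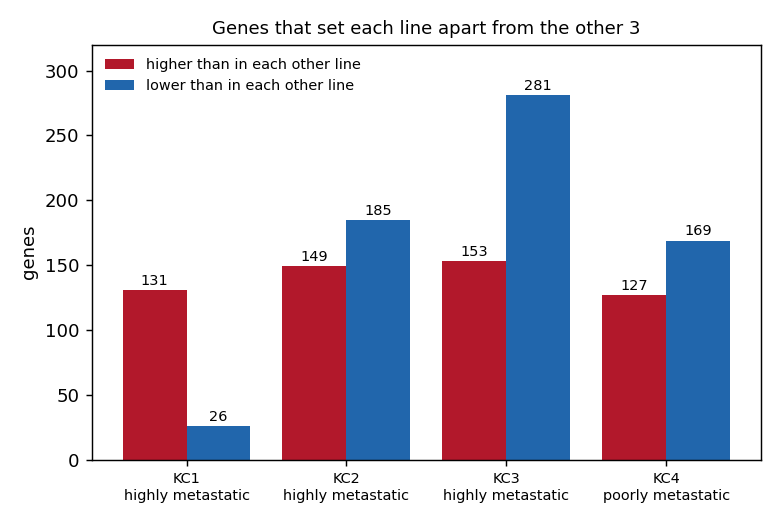
Number of genes (vertical axis) that set each cell line (horizontal axis) apart from each of the other 3, split into genes higher (red) and lower (blue) in that line. KC3 has the largest total, with 153 higher and 281 lower (304 and 195 with median centring), and KC4 has 127 and 169.

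The number of genes called between 2 lines did not separate pairs of the same class from pairs of both classes. Between KC4 and the others 1008 (KC1), 1725 (KC2) and 1496 (KC3) genes were called, and within the highly metastatic class 911 (KC1 and KC2), 1494 (KC1 and KC3) and 1972 (KC2 and KC3). KC2 and KC3, both highly metastatic, were the pair with the most calls. At a log2 difference of at least 2 KC2 and KC4 had the most, 486 against 478 for KC2 and KC3. The direction of calls in 4 of the 6 pairs turned with median centring. Quantile normalization turned that of KC2 minus KC3 alone (930 higher and 975 lower). Median centring moved KC3 minus KC4 from 641 higher and 855 lower to 989 and 657, KC1 minus KC3 from 969 and 525 to 724 and 939, KC2 minus KC3 from 1073 and 899 to 744 and 1515, and KC2 minus KC4 from 913 and 812 to 818 and 949.

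The lists of epithelial and of mesenchymal genes were both called between the classes by camera. Of 37 measured epithelial adhesion and identity genes, 8 were higher in the highly metastatic lines, 0 lower, and 4 of the 8 set KC4 apart. These were Ap1m2, an epithelial sorting adaptor (11.97 ± 0.07, 12.02 ± 0.06 and 12.03 ± 0.05 against 9.35 ± 0.21), the tight junction genes Cldn4 (1.54 higher, SE 0.042) and Cldn3 (1.52, SE 0.055), and the protease gene Prss8 (1.81, SE 0.13). The list mean was 0.52 higher (limma camera adjusted p = 1.88e-07; adjusted p = 0.0936 with an estimated correlation). E-cadherin, Cdh1, was high in every line and was 13.91 ± 0.14 in KC4 against 13.43 to 13.65. Of 27 mesenchymal genes, 9 were lower in the highly metastatic lines, 0 higher, and 5 of the 9 set KC4 apart. These were the calcium-binding protein gene S100a4 (-3.28, SE 0.066), the intermediate filament gene Vim (-4.25, SE 0.16), Nt5e (-2.60, SE 0.084), N-cadherin, Cdh2 (-3.77, SE 0.078), and Ncam1 (-2.09, SE 0.13). The list mean was -0.93 (adjusted p = 2.72e-05; adjusted p = 0.0842 with an estimated correlation). Vim varied inside the highly metastatic class, from 6.74 ± 0.44 in KC2 to 11.93 ± 0.05 in KC1, against 13.65 ± 0.11 in KC4. With the line as a random block Vim (adjusted p = 0.153) and Cdh2 (0.0879) lost their calls, and Vim also with 2 groups and the line ignored (0.0647). Of 2 other Nt5e probe sets, 1 set KC4 apart as well (-3.49) and 1 was not called (-0.42). On line means the call of the mesenchymal list was lost (adjusted p = 0.154).

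The TGF-beta and the NRF2 and glutathione lists were called lower in the highly metastatic lines by camera at the preset correlation, with a minority of their members called. Of 30 TGF-beta pathway genes, 8 were lower and 2 higher, with a mean of -0.67 (camera adjusted p = 0.0229; adjusted p = 0.147 with an estimated correlation). Bmp4, the activin antagonist Fst (-3.35, SE 0.17), and the BMP-induced genes Id3 (-2.13, SE 0.11) and Smad6 (-2.38, SE 0.13) set KC4 apart as higher. The latent TGF-beta binding protein gene Ltbp3 set it apart as lower (1.95 higher in the others, SE 0.062). The call of the TGF-beta list was lost without KC2 (adjusted p = 0.0515), without the dimmer 50% of the genes (0.153) and on line means (0.275). With the line as a random block Fst (adjusted p = 0.175) and Id3 (0.0689) lost their calls, and Fst also with 2 groups (0.0707). Of 38 NRF2 and glutathione genes, 8 were lower and 1 higher, with a mean of -0.55 (camera adjusted p = 2.72e-05, and 0.0958 with an estimated correlation). The list mean minus that of KC4 was -0.30 in KC1, -0.51 in KC2 and -0.84 in KC3. In KC3 5 members were lower than in each other line, and the list lay -0.57 from the mean of the other lines. Aldh3a1, the quinone reductase Nqo1 (-2.36, SE 0.31), the glutathione transferase Gsta2 (-1.83, SE 0.14), Aldh1a1 (-1.32, SE 0.28) and Gclm, a subunit of the first enzyme of glutathione synthesis (-1.58, SE 0.078), set KC4 apart. With the line as a random block Nqo1 (adjusted p = 0.113) and Aldh1a1 (0.357) lost their calls.

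The means of 3 lists of proliferation and lipid synthesis genes were lower in the highly metastatic class, mostly through KC3, although few or no members were called. The mean over 29 cholesterol and fatty acid synthesis genes was -0.56 (camera adjusted p = 1.51e-11; adjusted p = 0.0842 with an estimated correlation). Of its members 2 were called, Mvd (-1.5, SE 0.10) and Fdft1 (-1.01, SE 0.080), and 0 set KC4 apart. The mean over 35 DNA replication genes was -0.43 (adjusted p = 4.46e-09; adjusted p = 0.0842 with an estimated correlation). Of these 2 were called lower, of which the cyclin gene Ccne2 (-1.76, SE 0.075) set KC4 apart. The mean over 37 mitotic genes was -0.34 (adjusted p = 4.46e-09; adjusted p = 0.112 with an estimated correlation), with 0 called. KC3 minus KC4 gave -1.24, -0.91 and -0.74 for the 3 lists, KC1 minus KC4 -0.27, -0.089 and -0.15, and KC2 minus KC4 -0.18, -0.29 and -0.14. Fdft1 lost its call without KC3 (-0.16) and with the mean of its probe sets (-0.45). It also lost it at -0.95 to -1.0 without any of 4 single arrays, 1 of each line, and with quantile normalization, median centring or the pseudocount. Without KC3 the list means were -0.22, -0.19 and -0.14, with adjusted p of 0.0139, 0.0247 and 0.0139.

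**Figure D3:**
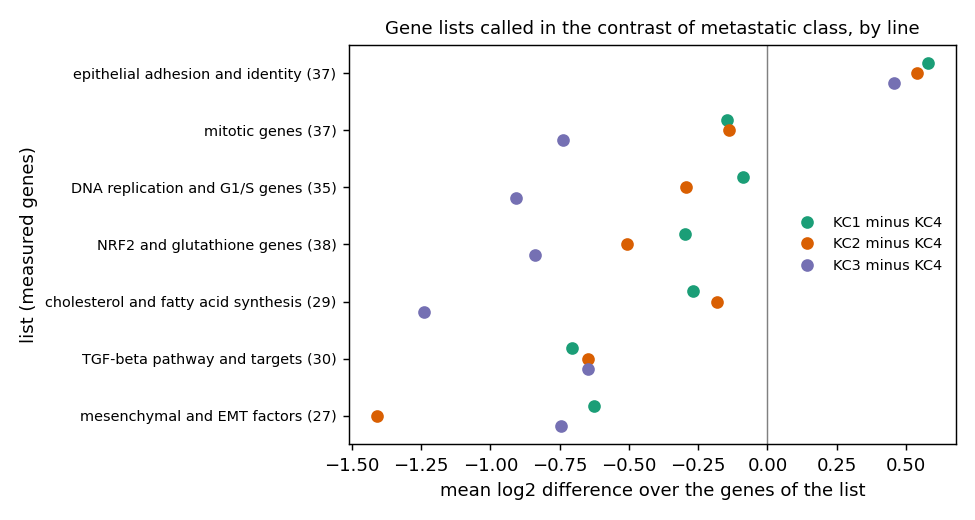
Mean log2 difference from KC4 (horizontal axis) over the measured genes of the 7 lists called between the classes (rows, with the number of genes), 1 point per highly metastatic line. The cholesterol, DNA replication and mitotic lists lie farthest from 0 in KC3 (-1.24, -0.91 and -0.74), and the mesenchymal list in KC2 (-1.41).

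The other 27 lists were not called by camera, though single members were. Of 39 collagen and matrix genes, 3 were higher and 5 lower (adjusted p = 0.176). The collagen-modifying enzyme Plod2 was 3.41 higher, and Col6a1 (-3.38), P4ha3 (-3.0) and the basement membrane collagen Col4a2 (-1.34) lower. Of 31 matrix protease and inhibitor genes, 2 were higher and 4 lower (2 and 5 adjusted over the list alone; adjusted p = 0.439). The collagenase Mmp13 was 3.70 and the plasminogen activator Plau 1.94 higher, and the inhibitor Timp3 was -4.57. Of 19 basal and squamous genes, 1 was higher and 5 lower (adjusted p = 0.103), with Krt14, Krt17 (-1.30) and Sprr1a (-1.71) setting KC4 apart. The Krt17 difference vanished at a floor of 64 (-0.01). Of 28 alveolar and club cell genes, 4 were higher and 3 lower (adjusted p = 0.762), among them Cebpa (3.32) and Muc1 (1.88), the one member of 20 mucin and goblet genes that set KC4 apart (2 higher, adjusted p = 0.424). Nkx2-1, the lung lineage factor, stayed between 4.18 and 5.41 in all lines. Of 41 cytokine genes, 5 were higher and 1 lower (5 and 2 adjusted over the list alone; adjusted p = 0.271), with Csf2 and Cxcl10 (-2.52) setting KC4 apart. Of 33 angiogenic and growth factor genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone; adjusted p = 0.152), with Fgf18 (-2.28, adjusted p = 0.0372 against KC1) and Vegfd (-1.53) setting KC4 apart. Fgf18 no longer did so when every probe set was tested. At a floor of 64 Cxcl10 (-0.74) lost its call, as did Mettl7b of the KC1 genes (-0.74) and Tppp3 of the ciliogenesis list (-0.21). The differences of Cdh2, Col6a1, P4ha3, Itga5, Timp3, Cebpa, Krt17, Cxcl10, Fgf18, Nqo1 and Tppp3 are lower bounds in size, with 1 (Timp3, Cebpa, Nqo1 and Tppp3) to 8 (Cxcl10) arrays of the lower side at the floor. Those of Nid1 (2 KC4 arrays and 1 other) and Cdkn2b (1 and 2) are not exact either, with floor values on both sides. With the mean of a gene's probe sets, Jag1 (0.97), Rfx3 (0.59), Krt17 (-0.78) and Kdm5d (0.81) lost theirs.

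Several signalling lists held few called members. K-ras and MAPK output genes had 2 of 26 higher (adjusted p = 0.0883), Spred3 (1.17) and Myc (1.07), and Myc lost its call without KC3 (0.51). Of 25 p53 target genes 1 was higher, Trp53inp1 (1.53), and 2 lower, among them Sulf2 (-3.26; adjusted p = 0.277). Of 35 Wnt genes 3 were higher and 1 lower, Axin2 (-2.23; adjusted p = 0.979). Of 23 YAP/TAZ targets 1 was higher and 2 lower, among them Nt5e (adjusted p = 0.371). Of 21 Notch genes 2 were higher, Jag1 (1.35) and Dtx4 (1.27; adjusted p = 0.138). Of 37 interferon-stimulated genes 3 were higher and 3 lower, among them Cxcl10 (adjusted p = 0.424). Of 32 hypoxia and glycolysis genes 1 was higher, Slc16a3 (1.04; adjusted p = 0.371). KC2 decided this value, since it was -0.01 without KC2. Slc16a3 also lost its call at 0.98 and 1.0 without KC3 replicates 2 and 3 and at 0.92 without KC1. Of 19 genes on the CDK inhibitor and senescence list, Cdkn2b was 3.99 higher and 2 were lower, among them Mtap (-1.60, list camera adjusted p = 0.152). Cdkn2b was as low in KC1 as in KC4 (4.19 ± 0.34 and 4.42 ± 0.40, against 10.51 ± 0.04 and 10.50 ± 0.02).

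The remaining lists held laminins and basement membrane genes (1 of 18 higher, Nid1 at 3.93, camera adjusted p = 0.103). Of 17 integrins 1 was lower (camera adjusted p = 0.371), Itga5 at -1.79, which lost its call without KC2 at -0.83. Of 23 gut-like and embryonic genes 3 were higher (camera adjusted p = 0.371), among them Cldn2 at 3.13 and Cldn6 at 1.18. Cldn6 was 0.70 and not called without KC2. Neuroendocrine genes had 1 of 17 higher and 1 lower, Ncam1 (camera adjusted p = 0.706). Ciliogenesis genes had 1 of 17 higher, Rfx3 at 1.43, and 1 lower, Tppp3 at -1.26 (camera adjusted p = 0.676). No gene was called among MHC class I genes (0 of 19; adjusted p = 0.104), imprinted growth genes (0 of 22; 0.371) and Hox genes (0 of 35; 0.912). Markers of other cell types that cultures could hold showed 1 of 24 leukocyte genes higher, Fcgr3 (1.36; adjusted p = 0.901). They showed 0 of 16 endothelial genes (0.901) and 0 of 20 fibroblast and smooth muscle genes (0.965). Further probe sets with a mean over 6 did not reach a call for Cldn2 (7.69, 8.28 and 7.25 against 7.51, difference 0.23), Sulf2 (-0.35), Jag1 (0.54), Trp53inp1 (0.99) and Fdft1 (0.31 and -0.96). With the line as a random block 36 named genes lost their call. Besides those given above they were Mvd, Fdft1, Nid1, Itga5, Timp3, Mmp13, Cebpa, Cldn2, Cldn6, Krt17, Fcgr3, Sulf2, Spred3, Myc, Axin2, Jag1, Cxcl10, Fgf18, Vegfd, Slc16a3, Rfx3, Tppp3, Cdkn2b, Mtap and the 4 sex-chromosome genes (adjusted p from 0.0566 to 0.986). Besides Vim and Fst, the fit with 2 groups and the line ignored took the calls of Nid1, Itga5, Mmp13, Cldn6, Sulf2, Myc, Slc16a3, Fdft1 and Cdkn2b. It also took those of the 4 sex-chromosome genes. The limma adjusted p of these further genes ran from 0.059 (Mmp13) to 0.664 (Slc16a3). With an estimated correlation 0 of the 34 lists were called. Counts adjusted over the list alone equalled those over all genes except where both are given. Median, mean and test direction differed in sign for the alveolar (-0.10, 0.12, down), cytokine (-0.04, 0.25, up), gut-like (-0.02, 0.18, up), fibroblast (-0.02, 0.02, down), leukocyte (-0.12, 0.04, up), Wnt (-0.04, 0.009, up), imprinted (-0.04, 0.15, up) and endothelial lists (mean -0.01, up).

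The sex-chromosome genes split the lines in a way that the metastatic classes do not follow. Xist, the RNA that silences one X chromosome in female cells, had a signal of 170 ± 28.0 in KC1 and 187 ± 52.8 in KC2 against 14800 ± 245 in KC3 and 11400 ± 582 in KC4. The Y-linked genes Eif2s3y (1320 ± 46.3, 157 ± 34.0, 10.7 ± 15 and 14.4 ± 14.2), Kdm5d (821 ± 58.5, 172 ± 32.9, 27.2 ± 12.2 and 23.1 ± 7.71) and Uty (1130 ± 72.0, 192 ± 20.4, 21.9 ± 3.65 and 26.0 ± 6.88) were highest in KC1 and lower in KC2. All 4 measured genes of this list were called between the classes, 3 higher and 1 lower (camera adjusted p = 0.152).

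**Figure D4:**
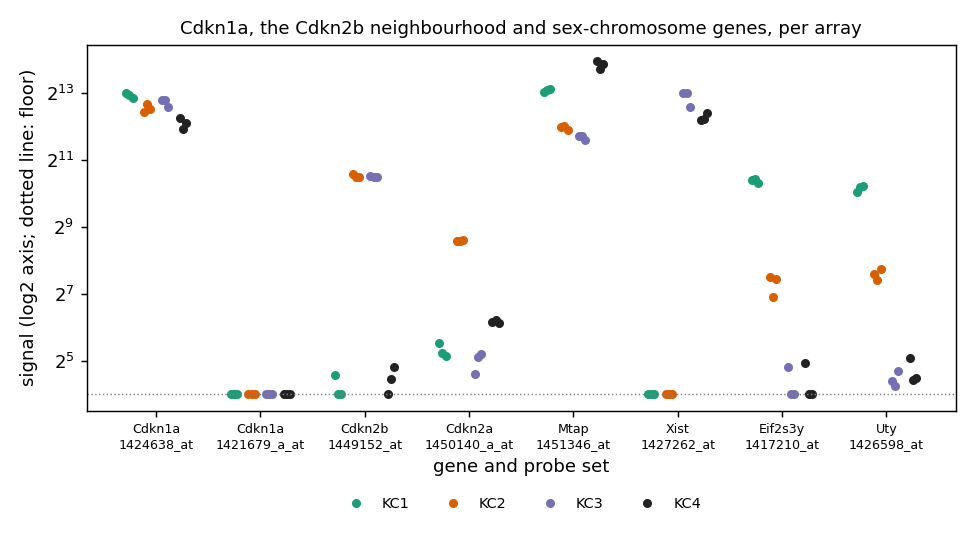
Signal per array (vertical axis, log2 scale, values under 16 drawn at 16) of 2 Cdkn1a probe sets, of Cdkn2b and its neighbours Cdkn2a and Mtap, and of 3 sex-chromosome genes, with 3 points per line. Cdkn2b is near the floor in KC1 and KC4 and at 1460 in KC2 and 1450 in KC3.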

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

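The test of RNA degradation was chosen only after the 18S result had been seen. No group held 4 to 10 samples, so single arrays were not tested as outliers.

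The highly metastatic lines did not all differ from KC4 in the same way. In 110 genes one highly metastatic line was called higher than KC4 and another lower. Hmgn3 (11.70, 11.83, 6.66 and 9.28 in KC1 to KC4) and Cavin2 (10.08, 11.67, 6.21 and 8.71) were high in KC1 and KC2 and low in KC3, Mdfic (10.70, 4.00, 4.00 and 6.35) was high in KC1 alone, and Cldn9 (6.06, 6.11, 12.44 and 8.25) in KC3 alone. Prl, the pituitary hormone prolactin, reached 13.96 in KC1 and 12.07 in KC3 against 6.03 in KC2 and 7.93 in KC4.

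The 5-prime control probe set for 18S ribosomal RNA, outside the genes tested, was 2.75 higher in KC4 on the log2 scale, with the lowest KC4 array at 2706 and the highest other array at 679. The middle and 3-prime probe sets were 0.84 and 0.66 higher. Degraded RNA would raise the 3-prime to 5-prime ratio of Actb and Gapdh in KC4 by over 0.5; the differences were -0.058 and 0.019, which argues against it. More ribosomal RNA carried into labelling, or a difference in ribosomal RNA between the lines, stays open and was not tested, and all KC4 arrays share it, so it cannot be separated from the line.

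Among 10092 probe sets without a single named gene, 80 set KC4 apart, 44 higher and 36 lower in the highly metastatic lines. The leading 2 in each direction were 7.03 and 5.0 higher, and -4.60 and -3.15, and each carried the ending of a probe set that can pick up related transcripts.

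The 296 genes that set KC4 apart were weighed against 3 technical explanations. Of 100 regroupings of the 12 arrays into 4 groups of 3, 3 gave as many genes, the real one included. The highest other gave 434, and the 2 others as large had a whole line as their group, while the highest without a whole line was 4. Groups that mix lines give few calls because arrays of one line resemble each other. The regroupings thus show that the arrays group by line and say nothing on chance between lines. If intensity-dependent compression were the cause, few calls would survive quantile normalization. Of the genes, 96.3% (285 of 296) stayed called. If fibroblasts left in the cultures were the cause of the genes higher in KC4, their abundant transcripts would be high there. The median difference of Col1a1, Col1a2, Col3a1, Dcn, Lum and Sparc was 0.34, against 2.18 for the median gene higher in KC4. Sparc differed most (1.91), through its low value in KC3 (6.39). It was 11.31 in KC4 against 10.28 in KC1 and 11.53 in KC2. Metastatic class, the individual tumour or mouse and any batch of the KC4 cultures stay open, since all coincide in this line.

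The other counts were set against regroupings in the same way. For the contrast of class 1 of 100 regroupings, the real one, gave as many as 991 genes (highest other 893, and 86 without a whole line as the group). For KC2 it was 1 (334 genes, highest other 97), and for KC3 2 (434 genes, highest other 454, in which a whole line was the group). Like the count for KC4, these show only that the arrays group by line. With lines as units 0 genes were called between the classes (smallest adjusted p 0.345), so chance between lines stays open. For KC1 5 of 100 gave as many as 157 genes (highest other 461), so chance is not excluded by this count. In 4 of the 5 another whole line was the group, and without such groups the highest was 1. These shares thus depend on how many of the drawn regroupings hold another whole line, for KC1 as for the other lines. The 10 splits of 2 lines are too few for a share under 0.05. With the arrays of the pair alone the real split, 1 of 10, gave 967, 1647 and 1409 genes for KC1, KC2 and KC3 against KC4 (highest other 1, 1 and 2). It gave 833, 1444 and 1886 for KC1 and KC2, KC1 and KC3, and KC2 and KC3 (highest other 6, 2 and 4).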

How the results depend on the processing

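The pseudocount of 16, the floor of 64 and the lists without each line were added after the data had been examined. Alternatives that kept the minimum difference, the genes tested and 1 coefficient per line left every total number of called genes within 1.5 times its main value, but not every number per direction. With median centring KC3 had 304 higher and 195 lower genes against 153 and 281, KC3 minus KC4 989 and 657 against 641 and 855, KC1 minus KC3 724 and 939 against 969 and 525, KC2 minus KC3 744 and 1515 against 1073 and 899, and KC2 minus KC4 818 and 949 against 913 and 812. Leaving out each array gave 965 to 1003 genes between the classes, 279 to 300 that set KC4 apart, and 7 called lists throughout. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated with a mean of -0.013 (-0.291 to 0.25 over 18 pairs, 3 over 0.1), and 3 of 12 arrays correlated best with their own number. With the replicate number as a block, 979 genes were called between the classes and 287 set KC4 apart, KC1, KC2 and KC3 had 150, 328 and 424, and 7 lists were called. The pairs had 992, 1708, 1459, 880, 1464 and 1948 in the order below.

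Pairs are given as KC1, KC2 and KC3 against KC4, then KC1 and KC2, KC1 and KC3, and KC2 and KC3. Without the dimmer 50% of the genes, with fewer genes tested by construction, 518 genes were called between the classes and 167 set KC4 apart; the pairs had 500, 1050, 887, 420, 856 and 1257, KC1 had 41 and KC2 194. The share of higher genes among those that set KC4 apart then rose from 57.1% to 71.9%. The filter uses the mean over all arrays, most of them from highly metastatic lines, so genes high in those lines pass it more readily. The rise is thus at least partly built in. At a log2 difference of at least 2 the share was 49.4% (40 of 81). With no minimum difference the counts were 5834 and 1807, pairs 4675, 6470, 6146, 4802, 6053 and 6901, and KC1 to KC3 751, 2401 and 2793. At a log2 difference of at least 2 they were 249 and 81, pairs 311, 486, 358, 252, 375 and 478, and KC1 to KC3 43, 74 and 77. With every probe set tested, which adds rows by construction, they were 2067 and 581.

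With 2 groups and the line ignored 511 genes were called. With the line as a random block (consensus correlation 0.559) it was 249, 61.0% of them higher against 52.8% with 1 coefficient per line. Neither fit measures the spread between poorly metastatic lines, of which there is 1. With line means as replicates KC4 is 1 value, so that fit shows no class difference. Whether the few lines or a lack of differences is the cause was not tested. An estimated correlation called 0 of 34 lists and fry 26, as fry does not compare a list with other genes. Lists that gained a call were hypoxia (adjusted p = 0.0154) and MHC class I (0.0341) without KC3, K-ras and MAPK (0.0099), p53 (0.0442) and collagens (0.0486) without KC2, and Notch (0.0323) without KC1. Others that gained were CDK inhibitors (0.029), growth factors (0.0299), mucins (0.0416) and basal genes (0.0445) without the dimmer genes, basal genes at a floor of 64 (0.0464), and collagens on line means (0.0222). The alveolar list, down by camera, was up by fry (mean 0.12). Slc16a3 turned to -0.014 without KC2. Without KC1, KC2 or KC3 the contrast of class gave 1148, 908 and 1201 genes, of which 47%, 51.8% and 57.8% were higher, so most were lower without KC1 (539 higher and 609 lower). Over named genes, 2564 of 2748 values kept direction and call, 182 lost the call, 1 gained it and 1 reversed. Signal over background limits dim genes: 789 of the 991 calls were kept at a floor of 64. The cause of other changes was not tested.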

Other observations

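The lists for each line against the mean of the other 3 were tested after the data had been examined; the test of neighbouring genes was not.

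Several lists were lower in KC3 than in the mean of the other lines by camera at the preset correlation. The dap control probe set was also lower in KC3, at 1021, 817 and 806 against 1416 to 1759 on the other arrays. The cre control was not, at 14672 to 18762 against 12967 to 16448. The dap difference ran along with every KC3 difference, and its cause was not tested. The member counts given here were not recomputed with median centring, under which fewer genes in all set KC3 apart as lower (195 against 281). Of 29 cholesterol and fatty acid synthesis genes, 12 were lower in KC3 than in each other line, with a mean of -1.09 (limma camera adjusted p = 1.11e-16; adjusted p = 0.0309 with an estimated correlation). Among them were Idi1 (10.37 ± 0.06 against 12.12 to 12.30 in the other lines), Fads2 (8.82 ± 0.12 against 10.68 to 10.94), Fdft1 (9.30 ± 0.20 against 11.60 to 12.08) and Mvk (6.12 ± 0.72 against 8.36 to 9.02). Of 35 DNA replication genes, 6 were lower in KC3 (mean -0.78, adjusted p = 6.62e-15; adjusted p = 0.0191 with an estimated correlation), although Myc, a driver of proliferation, was highest there (13.85 against 11.65 to 12.27). Of 37 interferon-stimulated genes, 7 were lower in KC3 (mean -0.88, adjusted p = 3.91e-07; adjusted p = 0.0618 with an estimated correlation), among them Dtx3l (6.36 against 9.36 to 9.65), Parp9 (6.26 against 8.34 to 8.50) and Ifi47 (4.56 against 7.25 to 7.86). The hypoxia and glycolysis list was lower in KC3 as well (4 of 32 members, mean -0.59, adjusted p = 0.00164; adjusted p = 0.233 with an estimated correlation), and the mesenchymal list in KC2 (5 of 27 members, mean -0.96, adjusted p = 0.00266; adjusted p = 0.326 with an estimated correlation).

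Cdkn2b, which encodes the cell-cycle inhibitor p15, had a signal of 17.7 ± 5.38 in KC1 and 20.5 ± 8.06 in KC4 against 1460 ± 41.0 in KC2 and 1450 ± 15.6 in KC3. Its neighbour Cdkn2a was 39.5 ± 5.59, 382 ± 3.28, 31.7 ± 6.71 and 71.6 ± 2.18 in KC1 to KC4. Mtap, next to Cdkn2a, ran the other way, with 8590 ± 189 in KC1 and 14600 ± 1170 in KC4 against 3960 ± 128 and 3250 ± 149, so the lines with the least Cdkn2b had the most Mtap. Beside Pgrmc1, low in KC4, the expressed neighbours Slc25a5 and Lonrf3 were 13.30 and 6.38 there, against 12.21 to 13.39 and 6.71 to 8.81 in the other lines.

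Copy-number differences of chromosome segments were weighed as a source of the genes that set a line apart. Of 1217 such genes with a place in the gene order, 5.75% (70) had a next measured gene that set the same line apart in the same direction, against 2.05% on average and at most 3.94% in 1000 shuffles of all lines together within levels of expression. By line it was 2.56% (4 of 156) in KC1, 7.51% in KC2, 5.31% in KC3 and 6.1% in KC4, and KC1 lay under the highest shuffle of all lines together. Shuffles were not run by line, so an excess is shown only for the lines together. With neighbours of like name left out it was 5.01%, against at most 3.62%. Such segments may thus account for a small part. Myc and its neighbour Pvt1 were both highest in KC3, but the next expressed gene on either side differed less. Lratd2 was 10.94 in KC3 against 9.93 to 10.31 in the other lines, and Cyrib 13.23 against 12.97 to 13.08. A larger segment is therefore not shown for this pair. The longest runs were 3 genes (Parp14, Dtx3l and Parp9 in KC3, and Il1r2, Il1r1 and Il1rl2 in KC2). Of these, Dtx3l and Parp9 belong to the interferon-stimulated list, which was lower in KC3, and the KC2 run holds genes of like name. In KC1 the Y-linked genes Kdm5d and Eif2s3y formed a pair. Shared regulation of neighbours, as for the pairs Col4a1 and Col4a2 or Cldn3 and Cldn4 in KC4, gives the same value and stays open.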
